A study of Caenorhabditis elegans with 11 samples.

How the data were processed

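Small RNAs of 18 to 32 nt from Caenorhabditis elegans were sequenced in 11 libraries of 7 groups. Sperm came from males of a him-8 strain, which makes many males, and oocytes from a fer-1 strain grown at 25 °C, where its sperm do not function. Per the labels' protocols, males were separated from hermaphrodites with a mesh filter, and sample purity, checked under the microscope, was above 95%. The other groups were wild-type (N2) embryos, N2 young adults, N2 animals of mixed stages, and young adults of the mutants eri-1(mg366) and glp-4(bn2). Sperm, oocyte, eri-1 and glp-4 each had 1 library sequenced by 454 and 1 by Illumina. N2 young adult had 1 library by 454, and embryo and N2 mixed stage had 1 each by Illumina. Groups and platforms were taken from the sample labels.

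Per the labels' protocols, each library started with 50 µg of total RNA, from which 18- to 32-nt molecules were selected, joined to a 5′ and then to a 3′ adapter, and amplified in 20 cycles of PCR. No step that removes 5′ triphosphates is described there. Secondary 22G siRNAs carry such a triphosphate and ligate poorly, so their level is understated in every library. The aligner, its version and the genome build are not given in the sources used here.

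The deposited files list the reads, 1 record per read, and the genomic hits of each read. Per the file headers, a hit has a percent identity, an alignment length, a start, an end, an e-value and a bit score, each with 1 value per hit. The identity values are percent values made by the authors' aligner, and the score values are bit scores deposited for each hit. No column holds read counts, and reads per sequence were obtained here by counting records. At most 10 hits were listed for a read, so reads with more genomic places are split among 10 at most.

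Reads of 18 to 32 nt with a hit of 100% identity over their full length were kept. The design's exon-based assignment was not used here, for the reason given below. The number kept ranged from 18189 in the Illumina glp-4 library to 3295787 in the embryo library. They made up 64.1% to 89.6% of the 18- to 32-nt reads in the 454 libraries and 7.99% to 84.3% in the Illumina libraries. In the glp-4 Illumina library 95.2% of all reads were 36 nt long and were not used. A read with several hits was split evenly among them.

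Genes came from the Ensembl release 115 annotation of WBcel235, and target genes were its 22307 protein-coding genes, pseudogenes and lincRNAs. The files' positions did not match that build exactly, and no coordinates were converted. Annotated piRNA 5′ ends lay 15 to 40 nt away from the 21-nt reads starting with U in the best-covered stretches of chromosome IV. A read was therefore given to a gene only if its 5′ end lay in the span of exactly 1 gene at every displacement from 0 to 125 nt. Positions of 20 Mb and above on chromosome V, which were displaced much further, were left out of gene assignment. Whole gene spans were used, since exon edges cannot be placed at this precision, so whether a read lies in an exon, an intron or a UTR was not analysed here. Gene positions are given by chromosome only. Where positions are printed, they are those of the files, whose build is not given in the sources used here. miRNA hairpins closer than 150 nt on a strand were counted as 1 feature, which gave 238 features from 261 annotated miRNA genes. In 21 features whose seed is well known, 87.7% to 100.0% of the reads carried that seed.

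The classes other than 21U were set before the data were examined, as were the tests, the library size, the minimum of reads, the lists and the rule for named genes. 26G and 22G reads are 26 and 22 nt long and start with G. 21U reads, the piRNAs of the worm, were taken as 21-nt reads starting with U outside miRNAs, a definition taken after the positions were examined, because piRNA gene positions could not be matched. miRNA reads are 18 to 26 nt long and sense to a hairpin. Shares are percentages of kept reads that are not sense fragments of rRNA, tRNA, snRNA or snoRNA, called non-structural reads. These numbered 18175 to 3269442 per library. Shares have 95% Wilson intervals, ratios have exact 95% binomial intervals, and levels scaled to 1000000 non-structural reads (RPM) have exact 95% Poisson intervals. The floor for a count of 0 is 3 reads per library. Intervals and floors cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

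The tests planned for a column of counts were replaced by the test planned for files without one. The planned count model, edgeR quasi-likelihood, was not used, since no column of the files holds counts. The design had assumed such a column and up to 50 hits per read. For each feature with at least 20 reads over the 11 libraries, limma 3.58.1 in R 4.3.3 was fitted to log2(RPM + 1) with a term per group and a term for the platform. All 11 libraries entered 1 fit, with 3 residual degrees of freedom, which come from the 4 groups sequenced on both platforms. Groups with 1 library are assumed to vary like these. siRNAs were counted antisense to genes, over the non-structural reads. miRNAs were scaled to miRNA reads with TMM factors, recomputed here with 30% of ratios and 5% of levels trimmed at each end. p-values were adjusted by the Benjamini-Hochberg method, and a call is an adjusted p below 0.05. Where a group has 0 reads, the log2 change rests on the added 1 RPM. In most libraries that is less than 1 read, so the log2 change can exceed the fold that the counts bound. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Where both libraries of a group had 0 reads, as in sperm, eri-1 and glp-4 for many siRNA genes, that pair showed no spread. SEs and p-values of such genes can then be too small. Before use, the 2 libraries of each group were compared over miRNAs. Their chi-square per degree of freedom was 91.9 to 396, so no pair held the same set of reads. Each pair was sequenced on different platforms, so this value cannot tell whether the 2 shared an RNA preparation.

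The fit was tested on simulated data with a dispersion of 0.1, in 20 simulations per comparison. Each feature was given 1 mean rate over all libraries, scaled to library size, without a platform effect or groups lacking reads. 16-fold changes were called for 11.4% of changed genes in the 26G comparison of sperm with oocytes and for 48.0% of changed miRNAs in that comparison. The share was 0% for 26G siRNAs in embryos against oocytes, 12.0%, 1.37% and 2.74% in the 3 comparisons of 22G siRNAs, 16.0% for miRNAs in embryos against oocytes and 25.4% for miRNAs in glp-4. At most 0.789% of unchanged features were called. The libraries differ from this setting, since some groups lack reads for many siRNA genes, so these shares may not hold for them. A count of 0 calls is not taken to exclude changes of 16-fold.

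Named features are up to 12 higher and 12 lower per comparison, ranked by size of change. They needed an adjusted p below 0.05, at least 50 reads in the higher group, the same direction on each platform and at most 50% of reads shared with other genomic places, above which a feature is named only as uncertain. Called members of the lists were added, at most 4 per list, and every tested member of the miRNA lists. Features named outside this rule are said to have been chosen after their values were seen. The 6 miRNA lists were the mir-35, mir-51, let-7, lin-4 and mir-58 families and markers of body cells. The 7 gene lists were major sperm proteins, sperm genes, oocyte and egg genes, ERGO-1 pathway targets, body genes, histone genes and germline core genes. Lists were tested with two-sided Fisher exact tests. The ERGO-1 list came from the literature and may rest partly on these libraries.

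The alternatives were other library sizes, TMM factors for siRNAs, no minimum of reads, only reads with 1 genomic match, no platform term, reads 1 nt shorter and longer, each library of a doubly sequenced group left out, N2 young adult and mixed stage as 1 group, other denominators and thresholds. A pseudocount of 10 RPM, voom weights, 26G loci in place of genes, and a fit without the eri-1 and glp-4 libraries were added after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used for counting and exact tests.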

Results

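The series profiled small RNAs in the germ cells, embryos and mutants of C. elegans. Its title names 26G endo-siRNAs, which are 26 nt long, start with G and are made antisense to messenger RNAs, in the regulation of spermatogenic and zygotic genes. Reads with a perfect genomic match numbered 117299 and 498234 for sperm, 178348 and 1184884 for oocytes, 185395 and 325453 for eri-1 and 179551 and 18189 for glp-4, by 454 and Illumina in that order. N2 young adult had 248869 reads by 454. Embryo had 3295787 and N2 mixed stage 419314, both by Illumina. Sense fragments of structural RNA took 58.9% and 48.6% of the sperm reads, 7.82% and 9.25% of the oocyte reads and 0.0770% to 12% of the reads in the other libraries, so sperm shares rest on 48240 and 256107 non-structural reads.

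The first comparison asked how much of each small RNA class sperm, oocytes and embryos hold. 26G reads were most frequent in oocytes, at 2.13% (Wilson interval 2.06% to 2.20%) of non-structural reads by 454 and 3.90% (3.86% to 3.93%) by Illumina. Embryos held 2.0% (1.99% to 2.02%). Sperm held 0.535% (0.474% to 0.604%) by 454 and 1.19% (1.14% to 1.23%) by Illumina. The oocyte share was 3.98-fold the sperm share by 454 (exact interval 3.51 to 4.54) and 3.29-fold by Illumina (3.17 to 3.41), and 1.95-fold the embryo share (1.92 to 1.97). Among 26G reads inside genes, 94.9% and 95.5% were antisense in oocytes, 92.9% in embryos, and 81.1% and 72.6% in sperm. 21U reads were most frequent in sperm and least in embryos, with 5.63% (5.43% to 5.84%) and 4.71% (4.63% to 4.79%) in sperm, 2.28% (2.21% to 2.35%) and 2.57% (2.54% to 2.60%) in oocytes and 0.916% (0.905% to 0.926%) in embryos.

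No test was planned or run for these shares, and their intervals cover counting error only. With structural RNA in the denominator the log2 ratio of sperm over oocyte moved from -1.99 to -3.16 by 454 and from -1.72 to -2.54 by Illumina. It shrank to -1.22 and -0.18 when distinct sequences were counted and to -1.63 and -1.04 for 25 to 27 nt, so its size depended on the way of counting. Counted as distinct sequences, the embryo share exceeded the oocyte share, with a log2 ratio of 0.99 in place of -0.96.

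The mutants asked which classes need ERI-1, an exonuclease of the complex that makes 26G siRNAs, and which need germ cells, which glp-4(bn2) animals make in very small number at the restrictive temperature. 26G reads made up 0.128% (0.115% to 0.143%) of non-structural reads in N2 young adults, 319 reads in all. The eri-1 library on the same platform held 2 such reads, a share 119-fold lower (exact interval 32.5 to 983), and the glp-4 library held 5, a share 46.0-fold lower (19.5 to 143). Counted as distinct sequences, the log2 ratio of glp-4 over N2 was -3.40 in place of -5.53. 21U reads were less frequent in eri-1, at 2.05% (1.99% to 2.12%), than in N2, at 3.1% (3.04% to 3.17%). The glp-4 library held only 29, or 0.0162% (0.0113% to 0.0232%).

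By Illumina, eri-1 had 145 26G reads, or 0.0506% (0.0430% to 0.0596%), of which only 26.6% of those inside genes were antisense. That library held 0.543% 21U reads (0.517% to 0.571%), against 0.578% (0.555% to 0.601%) in N2 mixed stage, which held 0.791% 26G reads (0.764% to 0.818%). The glp-4 Illumina library held 2 26G reads and 1 21U read among 18175. N2 young adults and N2 mixed stage were sequenced on different platforms and at different stages, so each mutant library has 1 wild-type library on its platform, and the Illumina one is of mixed stage. The growth temperature of glp-4 is not given in the sources used here.

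**Figure D1:**
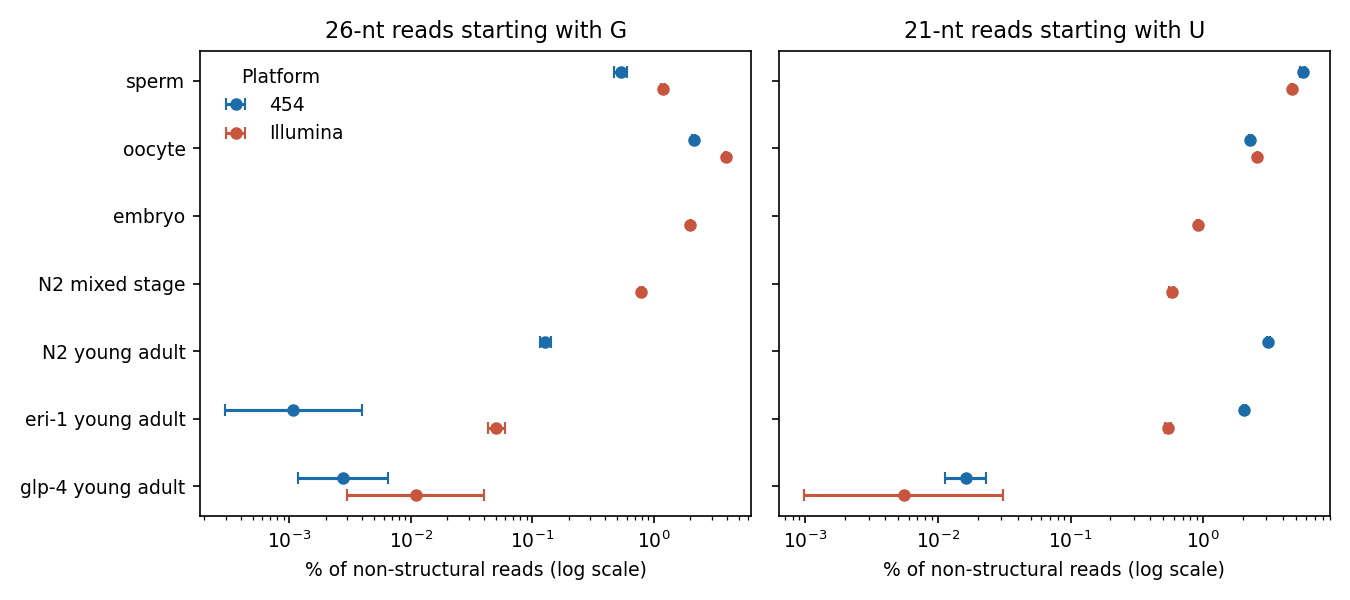
Shares of 26G reads (left) and 21U reads (right) in each library, as percent of non-structural reads on a log scale, with 95% Wilson intervals. The oocyte libraries have the highest 26G shares, 2.13% and 3.90%, and the sperm libraries the highest 21U shares, 5.63% and 4.71%. The glp-4 libraries lie lowest for 21U.

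The next comparison asked which genes are targeted in sperm and which in oocytes. Of 77 genes with enough antisense 26G reads, 54 were lower in sperm and 7 higher. The pseudogene E01G4.7 on chromosome II, a known target of the Argonaute ERGO-1, had 3003 RPM by Illumina in oocytes and 7.81 RPM in sperm, or 3229 reads against 2. That ratio was 385-fold (exact interval 106 to 3177), with a log2 change of -9.04 ± 0.89 (SE). The protein-coding genes F52G3.8 on X (log2 -8.05 ± 0.47) and F55C9.5 on V (-7.97 ± 0.25) had no sperm read, and were at least 36-fold and 22.5-fold lower in sperm by Illumina. The lincRNA linc-12 had 1393 oocyte reads and 5 sperm reads by Illumina, a 66.4-fold ratio (28.4 to 205).

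29 genes met the rule for named genes on the oocyte side, of which the 12 with the largest changes are named. Beside those above they were T05E12.8 (V, log2 -7.26), the pseudogenes F39E9.28 (-7.12) and F39E9.7 (-6.80), the lincRNAs linc-11 (-6.40), linc-8 (-6.35) and F39E9.10 (-6.05), all on II, F55C9.3 (V, -6.33) and Y57G11C.1144 (IV, -6.19). Their SEs ran from 0.25 to 1.54 and their adjusted p-values in limma from 0.000217 for F55C9.5 to 0.0167 for linc-8. F55C9.5 had 0 reads in the sperm, eri-1 and glp-4 libraries, so among the pairs only that of oocytes varied. E02H9.13 (III, -6.50) was uncertain, with 71.0% of its reads shared with other places. F55C9.3, Y57G11C.1144 and E02H9.13 had no sperm read, and were at least 6.83-fold, 9.12-fold and 9.73-fold lower in sperm by Illumina. F39E9.10 had no Illumina sperm read, and was at least 33-fold lower. With 0 sperm reads the log2 change rests on the added 1 RPM and exceeds these bounds.

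The 7 genes higher in sperm had under 50 reads each and are named here after their values were seen. By Illumina ZK1010.5 (III) had 35 sperm reads, dlc-6 (I), a dynein light chain, 22, and C25D7.16 (V) 18. None had an oocyte read, so they were at least 49.0-fold, 30.8-fold and 25.2-fold higher in sperm. K08F4.5 (IV) had 9 sperm reads and no oocyte read, and was at least 12.6-fold higher. K08C9.2 (I) had 16 sperm reads and 1 oocyte read, a 67.2-fold ratio (10 to 2817). klp-6 (III), a kinesin, and spch-3 (I), a sperm chromatin protein, were uncertain, with 91.4% and 79.9% of their reads shared.

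Without the Illumina oocyte library 30 of the 61 calls were left among 68 genes, and with voom weights 31 genes were called, 30 of them shared. Without the minimum of 20 reads, which the deep oocyte and embryo libraries meet more easily, the split was 35 higher and 31 lower among 1224 genes.

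**Figure D2:**
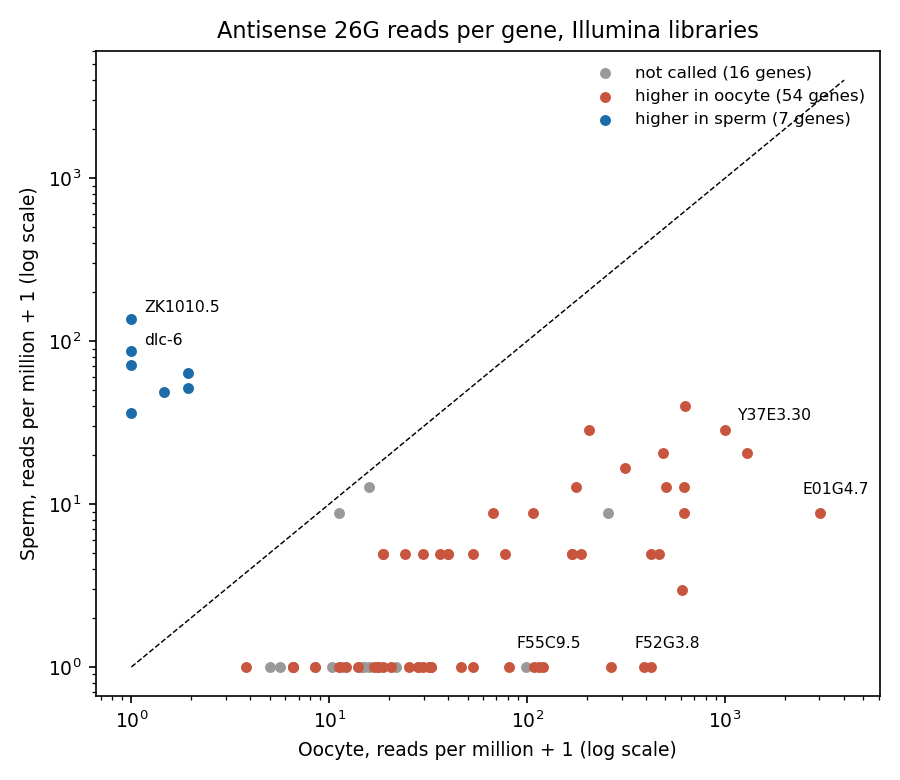
Antisense 26G reads in RPM plus 1 for the 77 tested genes in the Illumina oocyte library (x, log scale) and the Illumina sperm library (y, log scale), 1 point per gene, with the line of equality dashed. The 54 genes called higher in oocytes lie below the line and the 7 called higher in sperm above it.

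Among the gene lists, the ERGO-1 targets had 10 tested members, of which 9 fell in sperm. These 9 included E01G4.7, F55C9.5, F39E9.7 and F55C9.3. 9 were also called when adjusted over the list alone, which is not independent evidence if the list rests on these libraries. The share called did not differ from that of the other tested genes, 45 of 67 (Fisher exact p = 0.2656). The lists of major sperm proteins, sperm genes, oocyte and egg genes, body genes, histone genes and germline core genes had no member with enough 26G reads to be tested.

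Embryos were compared with oocytes to see whether the same genes are targeted before and after fertilization. By Illumina 61 genes had at least 10 RPM of antisense 26G reads in oocytes and 49 in embryos, out of 1315 genes with any such read. All 49 embryo genes were among the oocyte genes, against 2.27 by chance (Fisher exact p = 3.9e-78). Sperm had 138 such genes and shared 10 with oocytes, against 6.40 by chance (Fisher exact p = 0.133), and 9 with embryos (Fisher exact p = 0.0903). This depended on the threshold. At 25 RPM sperm shared 3 genes with oocytes, against 0.671 by chance (Fisher exact p = 0.027), and 3 with embryos, against 0.575 (Fisher exact p = 0.0179). At 5 RPM it shared 16 with each, against 18.2 and 14.7. Of the 1315 genes, 926 had a read in a sperm library, so this background is drawn largely from sperm. Overlap against all 22307 annotated target genes was not tested. In that wider background chance would give fewer shared genes than 6.40, so an excess shared by sperm and oocytes is not excluded. Genes are not independent replicates. 10 RPM corresponds to far fewer reads in sperm, where 1 read is 3.90 RPM, than in oocytes, where 1 read is 0.930 RPM.

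In level, limma called 0 of the 77 genes between embryo and oocyte, 6 had an unadjusted p below 0.05, and voom weights also gave 0. T08B6.2, a pseudogene on IV chosen after its values were seen, had the smallest adjusted p, 0.0775. It had 70.7 RPM in embryos and 11.2 RPM in oocytes by Illumina, a 6.33-fold ratio (exact interval 3.56 to 12.4), and 2 oocyte reads by 454. Of the 10 tested ERGO-1 targets 4 had positive and 6 negative fold changes, and 0 were called, also when adjusted over the list alone. Embryo had 1 library. 35 genes were called without the 454 oocyte library (9 higher in embryos, 26 lower), 26 without the Illumina one (19 higher, 7 lower) and 4 without either sperm library (2 higher, 2 lower), so the direction depended on the oocyte library kept, with fewer libraries to estimate the spread.

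The genes called in gametes were then read out in whole animals. This readout is not independent of the calls, since whole-animal reads counted toward the minimum of reads. K08F4.5, with 9 Illumina and 1 454 sperm read, met that minimum only through 8 reads in N2 young adults and 2 in N2 mixed stage. Pairs of eri-1 or glp-4 libraries with 0 reads also added no spread to the fit. Low levels in these mutants may therefore be partly built in. The 7 sperm-side genes together had 172 RPM (Poisson interval 125.3 to 233.1) in N2 young adults and 101 RPM (72.8 to 137) in N2 mixed stage. The 54 oocyte-side genes had 60.4 RPM (33.8 to 99.6) in N2 young adults and 2348 RPM (2204 to 2501) in N2 mixed stage. In eri-1 the 454 library had 0 reads over either set, which allows up to 16.3 RPM, and the Illumina library had 2 and 3 reads, or 6.98 RPM (0.846 to 25.2) and 10.5 RPM (2.16 to 30.6). In glp-4 both libraries had 0 reads over either set, which allows up to 16.7 RPM by 454 and 165 RPM by Illumina. Embryos had 7066 RPM (6975 to 7157) over the oocyte-side set and 1.33 reads over the sperm-side set.

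22G siRNAs, the secondary siRNAs made by RNA-dependent RNA polymerases, could be tested for 26 genes. In sperm against oocytes 9 genes were lower and 0 higher. E01G4.7 met the naming rule with a log2 change of -5.49 ± 0.41 (SE, limma adjusted p = 0.00111), with 68 Illumina reads in oocytes, none in sperm, and so at least 5.40-fold lower. The called ERGO-1 targets F39E9.7 (log2 -4.08) and E01G4.5 (II, -3.81) are named as members of their list. The others, named after their values were seen, were linc-22 (X, log2 -5.09, uncertain with 64.9% shared reads), linc-12 (-4.63), Y37E3.30 (I, -4.14), linc-7 (X, -3.76), T16A1.10 (II, -3.65) and sec-16A.1 (III, -3.09), a gene of the secretory pathway. All 3 tested ERGO-1 targets, E01G4.7, F39E9.7 and E01G4.5, were among the 9, against 6 of the other 23 (Fisher exact p = 0.0323), and 3 when adjusted over the list alone. That Fisher p was not adjusted for the other list tests, and the list may rest partly on these libraries. It is therefore not taken to show an excess of ERGO-1 targets. 1 histone gene was tested and not called.

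These 9 calls rest on few reads, and pairs of libraries with 0 reads add no spread to their fits. linc-12, E01G4.5, linc-7, T16A1.10 and sec-16A.1 had no sperm read on either platform, so the Illumina counts support only a change of at least 1.98-fold for linc-12, less for the next 3 and none for sec-16A.1. With voom weights and in the fit without the eri-1 and glp-4 libraries 0 genes were called, and without the Illumina oocyte library 1 of 6 tested genes was. Of the 22G reads inside genes, 71.2% were antisense in sperm by 454 (62 22G reads in all) and 30% by Illumina, against 84.8% and 86.9% in oocytes. For eri-1 against N2 young adults limma called 0 of 26 genes, 0 had an unadjusted p below 0.05 and voom weights gave 0. For glp-4 it called 0, with 1 at an unadjusted p below 0.05 and 0 with voom weights. That gene was linc-7, chosen after its values were seen, with 1 read in N2 young adults and 0 in glp-4. N2 young adults had 30 22G reads in all, glp-4 had 4 and 0, and eri-1 had 14 and 791, and few simulated 16-fold changes, 1.37% for eri-1 and 2.74% for glp-4, were called at this depth.

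miRNAs made up 78.8% to 99.9% of non-structural reads. In sperm against oocytes 1 of 105 tested miRNA features rose and 1 fell. mir-77 took 0.408% (0.352% to 0.472%) and 0.404% (0.377% to 0.433%) of miRNA reads in sperm and 0.00643% (0.00349% to 0.0118%) and 0.00489% (0.00368% to 0.00650%) in oocytes, a log2 change of 5.90 ± 0.94 (SE, limma adjusted p = 0.0476). mir-8199 (log2 -4.93), chosen after its values were seen, had 48 reads in oocytes and 0 in sperm. It may lie opposite a 26G locus, as far as the displaced positions allow. Leaving out single libraries gave 0 calls without a sperm, oocyte or eri-1 library and 17 or 18 without a glp-4 library. Voom weights gave 23 calls and the fit without eri-1 and glp-4 gave 26, and 28 features had an unadjusted p below 0.05.

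The family of mir-35, which is needed in embryos, had the largest share difference by level. Hairpins mir-35 to mir-41 took 39.7% (39.50% to 39.98%) and 25.8% (25.7% to 25.9%) of miRNA reads in oocytes, and 1.30% (1.19% to 1.41%) and 0.749% (0.712% to 0.787%) in sperm. Their log2 change was -5.27 ± 1.47 (limma adjusted p = 0.0894). The feature of mir-42 to mir-44 had -2.80 and was uncertain, with 97.0% of its reads shared with other places. Of its hairpins mir-43 and mir-44 are not on the list. Neither feature was called over all features, and 2 of 2 were when adjusted over the list alone, 1 of them this uncertain one. In the let-7 family, timing regulators of development, mir-48 took 20.5% and 10.8% in sperm and 1.17% and 0.600% in oocytes, with a log2 change of 3.90. The values were 3.70 for mir-241, 1.92 for let-7 and -0.32 for mir-84, and 2 of 4 were called, higher, when adjusted over the list alone.

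The other lists had no call over all features. In the mir-58 family the log2 changes were 0.57 for mir-58a, 5.02 for mir-58b with mir-58c, 1.5 for mir-80, 0.04 for mir-81 and -0.21 for mir-82, with 1 of 5 called, higher, when adjusted over the list alone. lin-4 had 2.47 and mir-237 1.74, and in the mir-51 family mir-51 had -1.45, mir-52 -0.60, mir-53 -0.42 and mir-54 to mir-56 -0.74, with 0 calls in either family. The body cell markers mir-1 of muscle (-0.58), mir-124 of neurons (-0.75), mir-228 of glia (-0.81) and mir-60 of gut (-0.16) were not called either. A lack of calls between sperm and oocytes cannot tell whether RNA of body cells was present in both. By 454, mir-1 took 3.56% of miRNA reads in sperm and 3.31% in oocytes, against 2.86% in N2 young adults. By Illumina it took 4.67% in sperm and 7.98% in oocytes, and N2 young adults had no library on that platform to set against these.

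Between embryo and oocyte limma called 0 of 105 miRNA features, 13 had an unadjusted p below 0.05 and voom weights gave 16 calls. lin-4 (log2 -6.26 ± 1.103) and let-7 (-6.03 ± 1.101) had the smallest adjusted p, both 0.0626. lin-4 took 0.000191% of miRNA reads in embryos, 6 reads, and 0.0315% and 0.0358% in oocytes. let-7 took 0.00137% in embryos and 0.215% and 0.253% in oocytes. Adjusted over the list alone, 4 of 4 let-7 family members were called lower in embryos (mir-241 -4.16, mir-84 -3.61, mir-48 -3.34) and 2 of 2 of the lin-4 family (mir-237 -4.46). mir-35 to mir-41 held 35.4% of miRNA reads in embryos (log2 1.26). The uncertain feature of mir-42 to mir-44, with 97.0% of its reads shared, had 1.06.

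The other lists had no call in embryos, also when adjusted over the list alone. Log2 changes were 1.36 for mir-58a, 1.35 for mir-58b with mir-58c, 0.27 for mir-80, 0.36 for mir-81 and 0.13 for mir-82. They were 2.19 for mir-51, -1.42 for mir-52, -2.34 for mir-53 and 0.42 for mir-54 to mir-56. Among body cell markers mir-1 had -0.58, mir-124 3.26, mir-228 -0.86 and mir-60 -1.37. With non-structural reads as the library size mir-80, mir-81, mir-82, mir-42 to mir-44 and mir-54 to mir-56 turned negative.

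For glp-4 against N2 young adults, which asks for miRNAs of the germline, limma called 0 of 105 miRNA features and 9 had an unadjusted p below 0.05, with 0 calls by voom weights. mir-796, chosen after its values were seen, had the smallest p, with a log2 change of -5.65 ± 1.18 (limma adjusted p = 0.261) on 8 reads in N2 and 0 in glp-4. mir-35 to mir-41 took 0.0569% (0.0469% to 0.0691%) of miRNA reads in glp-4 by 454 and 0.530% (0.502% to 0.560%) in N2 young adults, with a log2 change of -4.27 ± 1.88. The uncertain feature of mir-42 to mir-44, with 97.0% of its reads shared, had -0.52.

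No list had a call for glp-4, also when adjusted over the list alone. The let-7 family had log2 changes of -1.51 (let-7), -0.87 (mir-48), -1.99 (mir-84) and 0.57 (mir-241), and lin-4 and mir-237 had 0.45 and -1.49. The mir-58 family had 0.13 (mir-58a), -4.32 (mir-58b with mir-58c), -1.13 (mir-80), -0.19 (mir-81) and -0.23 (mir-82). The mir-51 family had -1.44 (mir-51), -1.19 (mir-52), -1.79 (mir-53) and -1.03 (mir-54 to mir-56). Body cell markers had -0.63 (mir-1), 0.62 (mir-124), -1.15 (mir-228) and -2.02 (mir-60). Without the 454 glp-4 library, 10 features were called, all lower.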

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

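The tests of sequencing depth and of 26-nt fragments in sperm were chosen only after the results they bear on were seen. The test of size selection was written before its result was seen.

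Many 26G reads lie where the comparisons per gene did not look, and they are given here because they stood above the eri-1 and glp-4 libraries, in which 26G reads are nearly absent. 26G reads in no gene by the rule used made up 66.5% and 62.2% of 26G reads in oocytes (454, Illumina), 59.2% in embryos, 45.4% and 26.0% in sperm, 31.4% in N2 young adults and 52.1% in N2 mixed stage. In all, 28 loci with under 10% of their reads inside a gene held 19851 oocyte reads by Illumina (18462 RPM) and 30562 embryo reads. The 4 libraries of eri-1 and glp-4 held 12 reads there, or 17.9 RPM. Above 20 Mb on chromosome V, 2 further loci held 3044 oocyte reads by Illumina, 5364 embryo reads and 1 read in the 4 libraries of eri-1 and glp-4.

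The 6 loci with most reads among these 28 are given as in the files, whose build is not given in the sources used here, with reads over the 11 libraries. They were II 3291637 to 3291793, minus strand, with 12980 reads, II 2136321 to 2137065, plus strand, with 8772, III 3829450 to 3831520, plus strand, with 6039, V 17073138 to 17073999, minus strand, with 4711, II 2094512 to 2094991, plus strand, with 4192, and X 17253188 to 17254274, minus strand, with 3600. The second of these lies opposite mir-8199, the III locus near C36A4.10 and C36A4.14, and the V locus opposite the non-coding RNA gene T05E12.10. Positions are displaced, so these genes are possible ones only. miRNA and other non-coding RNA genes were not among the target genes. If these reads do lie opposite mir-8199 and T05E12.10, they were given to no gene by construction, which was not tested. For the III locus the reason was not tested either.

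The first pattern weighed was the lack of 26G reads in the eri-1 and glp-4 libraries sequenced by 454. Sequencing depth was argued against. At the N2 young adult share, eri-1 would have held 237 reads and glp-4 230.2, and 2 and 5 were seen, with upper Poisson bounds of 7.23 and 11.7. A loss of longer molecules in size selection was argued against too, since 25- to 32-nt reads made up 14.3% (Wilson interval 12% to 16.9%) of structural reads in eri-1, 17.7% (13.4% to 23.1%) in glp-4 and 20.1% (16.6% to 24.2%) in N2. The mutations themselves remain as a hypothesis, with 1 library per genotype on this platform.

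The second pattern was that 26G reads in sperm lay in sense more often than in oocytes and embryos, of which breakdown of cellular RNA is a possible explanation. In the Illumina sperm library sense 26-nt reads starting with G were 1.109 times the mean of those starting with A, C and T (95% interval 1.01 to 1.22), as random fragments would be. Antisense reads starting with G were 48.46 times that mean (39.6 to 59.2), which fragments without a preferred first base do not give. By 454 the values were 2.991 (1.75 to 5.11), on 26.7 sense reads, and 28.34 (15.7 to 51.3). Breakdown was thus argued against for the antisense 26G reads in both libraries. For the sense ones it stays open by Illumina, and by 454 too few reads left it undecided, with a value above 2 and an interval that reaches below it. No biological explanation of the sense reads was tested. In the comparisons per gene, only antisense reads were used.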

How the results depend on the processing

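The pseudocount of 10, voom weights, 26G loci and the fit without eri-1 and glp-4 were chosen only after the data were seen. Of 1764 alternative values for 129 reported ones, 43 changed sign. The planned count model (edgeR quasi-likelihood) was not run on the counted records, since the design kept it for files with a column of counts. Where not stated, the cause of a change was not tested.

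For 26G siRNAs in sperm against oocytes 61 genes were called. Single libraries left out gave 30 to 64, with 30 without the Illumina oocyte library (68 genes tested) and 47 without the 454 one. Voom weights gave 31 (7 higher, 24 lower), TMM factors 43 (8 and 35), no minimum of reads 66 (35 and 31 of 1224 genes), loci 91 of 116 (11 and 80), a pseudocount of 10 gave 62 and the fit without eri-1 and glp-4 59. Of 25 genes named, 0 changed sign, 10 were called in every alternative in which they were tested and 15 lost their call in at least 1. The fit to loci holds no genes, and some genes fell below the minimum of reads when a library was left out. In embryos against oocytes 0 calls became 0 to 35 without single libraries, with 35 without the 454 (9 higher, 26 lower) and 26 without the Illumina oocyte library (19 higher, 7 lower) and 4 without either sperm library, 11 without a minimum, 1 without the platform term and 1 with a pseudocount of 10. T08B6.2 was called in 7 of 17 alternatives (adjusted p from 2.67e-06 to 0.997).

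The 9 calls for 22G siRNAs in sperm became 1 to 12 without single libraries, with 1 without the Illumina oocyte library (6 genes tested), 14 with reads 1 nt shorter and longer, and 0 with voom weights and without eri-1 and glp-4. Each of the 9 genes lost its call in at least 1 alternative. For eri-1 0 calls became 0 to 1 without single libraries, with 1 without either oocyte library, and 1 without a minimum. For glp-4 they became 0 to 2, with 2 without the 454 and 1 without the Illumina oocyte library, and 1 each with miRNA reads as library size, no minimum, no platform term and pooled N2. linc-7 there was 0.23 with voom weights. In some fits without a library, calls rest on genes with a spread of 0.

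The 2 miRNA calls in sperm became 0 to 18 without single libraries (18 without the 454 and 17 without the Illumina glp-4 library, 0 without any other), 10 with non-structural reads as library size, 23 with a pseudocount of 10, 23 with voom weights and 26 without eri-1 and glp-4. mir-77 stayed at 5.47 to 6.33. In embryos 0 calls stayed 0 without single libraries and became 1 with non-structural reads, 11 without a minimum, 1 without the platform term, 5 with a pseudocount of 10 and 16 with voom weights. For glp-4 they became 0 to 10, with 10 without its 454 library, and 1 with pooled N2.

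Log2 changes of miRNAs that changed sign, uncalled in either fit, were these without single libraries. In sperm, mir-124 ran from -1.83 to 0.32, mir-1 -1.41 to 0.25, mir-53 -1.07 to 0.23, mir-84 -1.14 to 0.51, mir-60 -0.74 to 0.41 and mir-81 -0.28 to 0.35. In embryos, mir-1 ran from -1.21 to 0.46, mir-54 to mir-56 -0.17 to 0.54, mir-81 -0.16 to 0.44, mir-80 -0.41 to 0.68 and mir-82 -0.29 to 0.21. In glp-4, mir-48 ran from -2.69 to 0.23, lin-4 -0.044 to 1.27, mir-82 -0.77 to 0.29, mir-81 -0.40 to 0.23 and mir-58a -0.34 to 0.53.

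With non-structural reads as library size, embryos gave -0.027 for mir-42 to mir-44, -0.67 for mir-54 to mir-56, -0.73 for mir-81, -0.82 for mir-80 and -0.96 for mir-82. Without eri-1 and glp-4 mir-81 was -0.28 in sperm, and in embryos mir-54 to mir-56 were -0.045, mir-81 -0.25, mir-80 -0.11 and mir-82 -0.42. For glp-4, pooled N2 gave 0.54 for mir-80, 1.21 for mir-82 and 0.77 for mir-81, no platform term -0.63 for mir-124, 0.11 for mir-82 and 0.088 for mir-81, and reads with 1 match 0.11 for mir-82 and 0.16 for mir-81.

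The log2 26G share of sperm over oocytes by 454, -1.99, was -3.16 over all matched reads, -1.63 for 25 to 27 nt and -1.22 for distinct sequences. By Illumina, -1.72 became -2.54, -1.04 and -0.18, and -1.54 over miRNA reads. Embryos over oocytes, -0.96, became -0.83 over all matched reads, -1.07 over miRNA reads and 0.99 for distinct sequences, for which depth was not matched. glp-4 over N2, -5.53, was -3.40 for distinct sequences, and eri-1 over N2, -6.89, was -6.89 to -7.08, within its counting interval. The overlap of oocyte and embryo genes and the whole-animal levels kept their direction in all alternatives run. Among the 1315 genes with a 26G read, sperm and oocytes shared 3 genes at 25 RPM (Fisher exact p = 0.027) and 16 at 5 RPM, where chance gives 18.2. In that background sperm and embryos shared 3 (Fisher exact p = 0.0179) and 16. Depth limits sperm and glp-4 most, where 1 Illumina read is 3.90 and 55 RPM.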

Other observations

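The tests on biotypes, on the sets of 26G genes and on the sequencing platform were chosen only after the results were seen. The test on eggs or embryos was written before its result was seen.

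By Illumina, genes with 26G siRNAs differed in kind between 1 sperm and 1 oocyte library. Of the 128 genes with at least 10 RPM of antisense 26G reads in the Illumina sperm library and below that in oocytes and embryos, 127 (99.2%) were protein-coding. Of the 51 genes at that level in oocytes and not in sperm, 25 (49.0%) were protein-coding, 17 (33.3%) were pseudogenes and 9 (17.6%) were lincRNAs (Fisher exact p = 4.09e-16 for protein-coding against other genes). Most sperm genes stand on few reads, since 1 read there is 3.90 RPM, and genes are not independent replicates. Only 32 of the 128 had a read in the 454 sperm library. Of all 138 sperm genes at 10 RPM, 131 (94.9%) were protein-coding. The share of protein-coding genes among all target genes was not compared, so the sperm share is not shown to be unusual.

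The sperm set was also seen outside sperm. It had 462 RPM in N2 young adults over 41 of the 128 genes, 344 RPM in N2 mixed stage, 0 reads in the 454 eri-1 library, 19.2 RPM (5.5 reads) in the Illumina one and 0 reads in either glp-4 library. The oocyte set had 36.2 RPM in N2 young adults and 1453 RPM in N2 mixed stage. ERGO-1 targets were 9 of the 61 oocyte genes (Fisher exact, BH-adjusted p = 1.61e-08 over 35 comparisons) and 8 of the 49 embryo genes (6.14e-08), and 0 of the 138 sperm genes, all at 10 RPM or more. That list may rest partly on these libraries, and without the minimum of reads the 26G split between sperm and oocytes was 35 higher and 31 lower. These list tests run only among the 1315 genes with a 26G read.

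Known sperm genes and ERGO-1 targets both carried antisense 26G reads in sperm more often than other annotated genes did, mostly at low levels. Of the sperm genes 16 of 57 (28.1%) had a read in at least 1 sperm library, against 910 of 22250 other genes (4.09%; Fisher exact, Bonferroni-adjusted p = 3.36e-08 over 42 tests), and 0 had one in oocytes. With only reads of 1 genomic match they were 13 (adjusted p = 5.31e-06). ERGO-1 targets with a sperm read were 6 of 16 (37.5%, against 4.13% of other genes; adjusted p = 0.00118), or 5 with reads of 1 match (0.00913), and 14 of 16 had a read in oocytes. The ERGO-1 list holds known siRNA targets and may rest partly on these libraries, and 0 of its members reached 10 RPM in the Illumina sperm library. Its excess therefore does not decide whether that of the sperm genes is special to them. Major sperm protein genes were 15 of 35 (adjusted p = 1.05e-10), but 3 of 35 with reads of 1 match (unadjusted Fisher exact p = 0.14), since these genes share reads. At 10 RPM or more in the Illumina sperm library there were 2 sperm genes, spe-10 and ssp-16 (adjusted p = 1), and 0 major sperm protein genes. Gene length and transcript level were not accounted for, and many of these genes stand on 1 read or a part of one. The count rests on the Illumina sperm library, since by 454 only ssp-16 had reads.

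1 locus given to no gene was read mostly in sperm. At I 15064506 to 15064644, plus strand, as in the files, 16 and 103 of its 120 reads came from the sperm libraries and 1 from oocytes.

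The third pattern weighed was a difference between the eri-1 libraries, in which mir-35 to mir-41 took 0.518% of miRNA reads by 454 and 7.47% by Illumina, a 14.4-fold ratio (exact interval 13.5 to 15.4). The platform was argued against by the sperm group, in which the same ratio was 0.578 (exact interval 0.524 to 0.638). In oocytes it was 0.649, but the 454 share there was already too high for a rise of this size. The oocyte ratio therefore could not decide this. Eggs or embryos inside the animals of the Illumina library are a possible explanation. The 12 other miRNAs enriched in oocytes had a median log2 ratio of 0.9496 (95% interval -0.69 to 2.59), with 7 above 0, so this was left open by too few miRNAs that went both ways. The labels call both libraries young adult, and no biological explanation beyond the stage was tested.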
